A study of Mus musculus with 29 samples.

How the data were processed

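Splenic CD4 T cells of C57BL/6 mice were profiled with the QuantSeq 3' mRNA-Seq FWD kit, which sequences tags near the 3' end of polyadenylated transcripts, from total RNA taken with TRIzol. The series holds 29 samples, of which 17 RNA libraries were used here. The cell-type experiment had 3 libraries each of naive CD4 T cells, of Th0 cells (cultured for 5 days with IL-2 at 15 ng/ml) and of Treg cells (cultured for 5 days with IL-2 at 15 ng/ml and human TGF-beta at 10 ng/ml). The Smad experiment had 2 libraries each of Treg cultures without a guide RNA (control) and with guides against Smad2 (sgSmad2), Smad3 (sgSmad3) or both (sgSmad2/3). The 4 RNA libraries of an Acsbg1 experiment and the 8 ATAC libraries were not analysed here. The labels do not say whether replicates came from separate animals or cultures, so each p measures the spread between these libraries, which may be technical. Replicate numbers did not pair libraries across groups of the cell-type experiment: the correlations of the deviations from the group means lay between -0.036 and 0.048 over genes. In the Smad experiment the control and sgSmad2 libraries of one number did share deviations (0.46 over genes) and the other pairs of groups did not (0.00040 to 0.095), so a replicate block was used as an alternative alone.

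The submitters' processing notes name STAR 2.7.9a, Subread 2.0.1, Bowtie2, deepTools and the build mm10, without a role or an order. The annotation version and the strand setting are not given in the sources used here. The authors deposited 1 table per experiment under the name TPM. In the cell-type table the deposited values were CPM, reads per 1000000 counted reads: all columns summed to 1000000, and 100% of the values were whole multiples of the worth of 1 read within a tolerance of 0.01, whatever the gene's length. In the Smad table the deposited values were a score, CPM rounded to whole numbers by the authors, with column sums of 1000167 to 1000923. An unnamed last line of that table, at most 7.7e-05% of a column, held the worth of 1 read in each library and was not treated as a gene. The plan made before the data were examined took both tables for TPM. All value columns were matched to a sample. Of the IDs, 54409 of 54532 in the cell-type table and 55154 of 55421 in the Smad table had a name in the reference table, and 27 symbols in each that a spreadsheet had turned into dates were restored from it.

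The reads worked out for the cell-type table were 797612, 807143 and 855458 for naive, 943873, 901206 and 816391 for Th0, and 928709, 1551478 and 1020894 for Treg libraries. For the Smad table the worth of 1 read gave 1541289 and 1433268 reads for control, 1512629 and 1493190 for sgSmad2, 1602297 and 1294583 for sgSmad3, and 1310993 and 1504588 for sgSmad2/3 libraries. At these depths a count of 0 allows a level of up to 3 reads per library, which is 3.76 CPM in the shallowest naive library. The reads carry no molecular identifiers, so such floors cover counting error only. Gm42418, a locus that overlaps ribosomal RNA, took 10.3% to 11.4% of the CPM in naive, 6.59% to 7.88% in Th0, 7.11% to 8.78% in Treg and 4.81% to 7.60% in the Smad libraries. Reads shared between paralogs (Hba-a1 and Hba-a2, Hbb-bs and Hbb-bt, the Ms4a, Ifit and Tcrg families) cannot be assigned with certainty.

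Genes were kept at 1 CPM or more in at least 3 libraries of the cell-type table (14165 of 19464 above 0) and at least 2 libraries of the Smad table (18347 of 22643 above 0). limma 3.58.1 in R 4.3.3 was fitted to log2(CPM + 1) with an intensity trend, all groups of a table in 1 fit, and p values were adjusted by Benjamini and Hochberg over the genes tested, with a threshold of 0.05. Folds are on this scale, which understates the change of genes with few reads. The contrasts were Treg against Th0, Treg against naive, Th0 against naive, each guide against the control, and the departure of sgSmad2/3 from the sum of the single guides. Genes higher in Treg in both of its contrasts were called Treg-specific. A set of 22 gene lists, fixed before the data were examined, was tested with camera at a preset correlation of 0.01, with adjustment over the lists of a contrast, and again with an estimated correlation and with fry. They covered Treg core genes, tissue Treg genes, TGF-beta and Smad targets, acyl-CoA synthetases, fatty acid synthesis, cholesterol synthesis, glycerolipid synthesis, fatty acid oxidation, oxidative phosphorylation, genes of the mitochondrial genome, glycolysis, cell cycle, effector T helper genes, naive and quiescence genes, interferon response, p53 targets, integrated stress response, immediate early genes, and markers of B cells, myeloid cells, CD8, NK and gamma-delta cells, and red cells. The genes higher and lower in Treg than Th0 by 2-fold or more (233 and 177) were tested as sets in the guide contrasts. The same fit gave sgSmad2/3 against each single guide and sgSmad3 against sgSmad2, and set tests of these and of the departure from additivity were adjusted over their 8 tests.

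The rule for named genes, also fixed before the data were examined, had 3 parts. Part a took Acsbg1, Acsl6, Smad2, Smad3 and Foxp3 whatever their values. Part b took up to 10 genes per direction with the largest change among those past the threshold, with groups that did not overlap and a mean of 5 CPM or more in the higher group, without predicted genes, clones, pseudogenes, mitochondrial genes and receptor segments. Part c took up to 4 members of each list past the threshold, or up to 2 where none passed. A gene outside the rule is named as chosen after its values were seen.

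Both fits were tested on simulated data, 5 tables per experiment with 200 changed genes. In the cell-type design limma made 157 to 179 calls, of which 3 to 5 were false, and recovered 59% to 77% of 2-fold and 91% to 97% of 4-fold changes. In the rounded Smad design the fit as planned made 17 to 277 calls with 0 to 203 false ones, over 100 in 3 of the 5 tables, and recovered 0% to 14% of 2-fold changes, with 368 to 438 genes that had no spread within any group. A stricter filter of 5 CPM, planned as an alternative, made 150 to 164 calls with 3 to 11 false ones and recovered 46% to 66% and 92% to 95%. With robust moderation the calls were 145 to 165 (6 to 12 false), and edgeR made 139 to 155 (2 to 7 false). Statements on genes and the 22 lists in the guide contrasts therefore rest on the 5 CPM filter (10737 genes). It was chosen after its counts and edgeR's were seen. Real replicates spread unequally (chi-square per degree of freedom 1.94 for sgSmad2/3, 5.79 for sgSmad2), so real false calls may be more. The sets of genes higher and lower in Treg than Th0 are from the fit as planned, whose set tests were not simulated. Its counts, and the 5 CPM values of the sets, are given beside.

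edgeR 4.0.16 (quasi-likelihood test with its default scaling factors) was run as an alternative on the recovered reads of the cell-type table and on approximate reads of the Smad table. It called 1066, 5808 and 5770 genes in the cell-type contrasts and 24, 185 and 201 in the guide contrasts on genes at 1 CPM, and 1, 15 and 71 in the latter on genes at 5 CPM, a fit added last. Other alternatives were pseudocounts of 0.1 and 5 CPM, no filter, the 5 CPM filter, median-ratio and quantile scaling, removal of mitochondrial and ribosomal protein genes or of ribosomal RNA genes, no trend, robust moderation, the replicate block, the compared groups alone, and leaving out each library. A pooled contrast of each guide (4 libraries with it against 4 without) was added after the single contrasts gave no gene under the fit as planned. Lists of transcripts of other tissues were written after the Smad table had been seen.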

Results

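The series asks whether genes of lipid synthesis are specifically higher in regulatory T (Treg) cells and what Smad2 and Smad3, the transcription factors downstream of the TGF-beta receptor, do for Acsl6. Gene expression was measured by 3' tag sequencing in 17 libraries of mouse splenic CD4 T cells. The cell-type experiment (797612 to 1551478 reads per library) had 3 libraries each of naive, Th0 (with IL-2) and Treg cells (with IL-2 and TGF-beta). The Smad experiment (1294583 to 1602297 reads) had 2 each of Treg cultures without guide RNA (control) and with guides against Smad2, Smad3 or both. Levels below are in reads per 1000000 (CPM), as mean ± SD over the libraries of a group (n = 3 for cell types, n = 2 for guides), and changes are on the log2 scale with the standard error (SE). A lone number in parentheses after a gene is its log2 change. Paired counts of a list give the higher members first and the lower members second. Positions are on GRCm38.p6.

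Treg cells were compared with Th0 cells, which lacked TGF-beta in the medium, for the genes the series is about. Acsbg1 (ENSMUSG00000032281, chromosome 9, 54604886 to 54661885), a protein-coding gene for an acyl-CoA synthetase that activates long-chain fatty acids, had 53.2 ± 4.37 CPM in Treg, 11.9 ± 4.20 in Th0 and 8.55 ± 2.56 in naive cells. It was 4.32-fold higher in Treg than in Th0 (log2 change 2.11, SE 0.31, limma adjusted p = 0.00014) and 5.79-fold higher than in naive cells (limma adjusted p = 1.7e-06). Th0 did not pass the test against naive cells for Acsbg1 (0.42, adjusted p = 0.29). Acsl6 (ENSMUSG00000020333, chromosome 11, 54303805 to 54364756), another protein-coding acyl-CoA synthetase, had 47.7 ± 21.0 CPM in Treg and 9.79 ± 1.31 in Th0, and was listed at 0 in all 3 naive libraries. It was 4.19-fold higher in Treg than in Th0 (2.07, SE 0.44, limma adjusted p = 0.0061). This call for Acsl6 was lost without Treg replicate 2 (1.88, adjusted p = 0.065), without Treg replicate 3 (1.81, adjusted p = 0.065) and with a pseudocount of 0.1 CPM (adjusted p = 0.082, in a range of 2.1e-09 to 0.082 over the alternatives). Against the naive floor of 3.76 CPM, which 3 reads make in the shallowest naive library, Acsl6 was at least 12.7-fold higher in Treg and at least 2.60-fold higher in Th0. Foxp3 (ENSMUSG00000039521, chromosome X, 7579676 to 7595243), a protein-coding gene for the transcription factor that defines Treg cells, had 179 ± 36.2 CPM in Treg, 10.4 ± 2.92 in Th0 and 87.8 ± 4.56 in naive cells. Its change from Th0 to Treg was 15.8-fold (3.99, SE 0.19, limma adjusted p = 2.3e-10). Smad3 (ENSMUSG00000032402, chromosome 9, 63646766 to 63757994, protein coding) was lower in Treg than in Th0 (26.6 ± 1.96 against 44.2 ± 8.04 CPM, -0.70, SE 0.19, limma adjusted p = 0.039). That Smad3 call was lost without Th0 replicate 1 (adjusted p = 0.079), Th0 replicate 2 (0.20), Treg replicate 1 (0.090), Treg replicate 2 (0.081) or Treg replicate 3 (0.14), without the trend (0.11), with quantile scaling (0.050) and with a replicate block (0.057), in a range of 0.027 to 0.20. Smad2 (ENSMUSG00000024563, chromosome 18, 76241090 to 76311748, protein coding) had 30.9 ± 3.04 CPM in Treg and 37.1 ± 7.14 in Th0 (-0.24, adjusted p = 0.69). Adjusted over these 5 genes, fixed before the data were examined, p was 4.2e-06 for Acsbg1, 0.00028 for Acsl6, 1.7e-13 for Foxp3, 0.0024 for Smad3 and 0.27 for Smad2 in Treg against Th0.

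**Figure D1:**
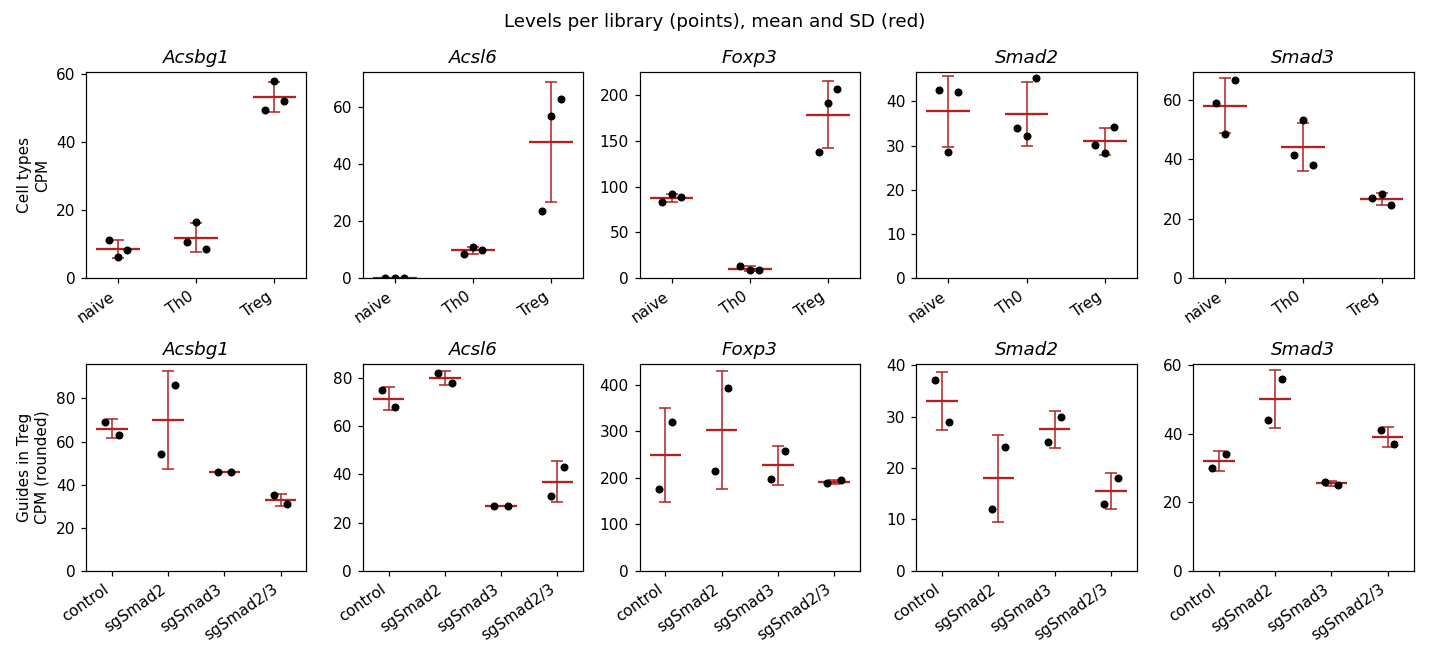
Levels of Acsbg1, Acsl6, Foxp3, Smad2 and Smad3 in CPM (vertical axes) for each library (points) with mean ± SD (red), by cell type in the upper panels and by guide in the lower panels, where values are rounded to whole CPM. Acsl6 was 0 in the 3 naive libraries, and 27 CPM in both sgSmad3 libraries against 75 and 68 in the controls.

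Genes that differed most between Treg and Th0 included Cdh1, Cx3cr1, Ctsw and Ldlrad4 (higher) and Gzmb, Tgm2 and Ms4a4c (lower). Higher in Treg were Cdh1, which encodes E-cadherin (150 ± 28.2 against 0.74 ± 1.28 CPM), Camk2n1, an inhibitor of CaM kinase II (115 ± 34.5 against 1.85 ± 0.55; 5.32, SE 0.40, limma adjusted p = 5.7e-08), and the chemokine receptor Cx3cr1 (74.5 ± 4.76 against 1.54 ± 0.79). So were Cd40, a receptor of the TNF receptor family (38.9 ± 11.1 against 0.78 CPM), and the protease Ctsw (323 ± 39.1 against 15.7 ± 2.15; 4.28, SE 0.19, adjusted p = 6.3e-11). The inflammasome sensor Nlrp6 (33.1 ± 10.3 CPM) and the TGF-beta inhibitor Ldlrad4 (28.4 ± 3.39) were listed at 0 in all 3 Th0 libraries. Lower in Treg were the cytotoxic protease Gzmb (16.1 ± 6.92 against 499 ± 97.3; -4.95, SE 0.47, adjusted p = 6.9e-07), the transglutaminase Tgm2 (6.18 ± 6.78 against 112 ± 22.3; -4.37), Nrn1 (6.76 ± 1.60 against 88.9 ± 3.22; -3.55) and Plac8 (15.2 ± 11.5 against 158 ± 32.7; -3.53). Ms4a4c had 99.2 ± 20.5 CPM in Th0 and 0 in all 3 Treg libraries. With limma 423 genes were higher and 347 lower in Treg among 14165 tested. The total of 770 became 503 without Treg replicate 2 and 453 without the trend.

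TGF-beta targets rose together in Treg: 8 of 24 measured members were higher and 0 lower than in Th0. The counts were 13 and 0 adjusted over the list alone (camera adjusted p = 3.2e-16, and adjusted p = 0.0023 with an estimated correlation). The 8 were Spsb1 (71.1 ± 15.5 against 1.46 ± 1.70 CPM), Ldlrad4, Itgae, Smurf2 (1.13) and 4 feedback regulators of the pathway, Pmepa1 (576 against 61.3 CPM, 3.28), Skil (3.11), Smad7 (90.1 against 14.5, 2.57) and Ski (222 against 81.9, 1.44). Of 27 Treg core genes 8 rose and 3 fell. This made 10 and 4 adjusted over the list alone (camera adjusted p = 0.00075, and adjusted p = 0.17 with an estimated correlation). Those that rose were Foxp3, Itgae (CD103, 28.3 ± 3.07 against 0.41 CPM), the ectonucleotidases Nt5e (2.87) and Entpd1 (2.07), Nrp1 (1.55), Lrrc32 (1.22), Ikzf4 (463 against 210 CPM, 1.14) and Capg (0.73). Those that fell were the costimulatory receptor Icos (70.2 against 166 CPM, -1.22), the repressor Prdm1 (-1.24) and the IL-2 receptor chain Il2rb (-0.36). Tissue Treg genes went both ways, with Itgae, Cxcr6 (2.83), Maf (111 against 43.5 CPM, 1.40) and Bhlhe40 (0.69) higher and Id2 (283 against 796 CPM, -1.48), Prdm1 and Gzmb lower among 17. The list gave 6 and 3 adjusted over the list alone (camera adjusted p = 0.40). Effector T helper genes had Runx3 (818 against 391 CPM, 1.06) and Il18r1 (1.03) higher and Gzmb, Ccl5 (2.49 against 22.6 CPM, -2.77), Gzmc (-2.07) and Il12rb2 (-1.86) lower among 25. The counts were 4 and 8 adjusted over the list alone (camera adjusted p = 0.12). Among 23 naive and quiescence genes 10 were higher, such as the transcription factor Klf2 (497 against 196 CPM, 1.35), S1pr1 (0.73) and Foxo1 (0.55), and 5 lower. The latter included Satb1 (356 against 908, -1.35), Dapl1 (68.5 against 236, -1.80), Slfn2 (-0.79) and Tcf7 (-0.67). That list had 12 higher and 5 lower adjusted over the list alone, with a camera adjusted p of 0.0036, and adjusted p = 0.33 with an estimated correlation. Members of a list named here and below because 5 or fewer passed, and those outside the rule for named genes, were chosen after their values were seen. Of the genes named in this paragraph, calls were lost in some of the 6 fits that left out 1 library for Entpd1 (5 fits, adjusted p up to 0.19), Capg (5, 0.14), Il2rb (5, 0.18), Bhlhe40 (5, 0.11), Prdm1 (4, 0.10), Gzmc (3, 0.14), Il12rb2 (3, 0.14) and Foxo1 (3, 0.078).

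Of the lipid genes the series is about, 2 acyl-CoA synthetases differed between Treg and Th0, and the lists of fatty acid and cholesterol synthesis had no member past the threshold. Acsbg1 and Acsl6 were the 2 of 14 acyl-CoA synthetases that rose and 0 fell. This made 2 and 1 adjusted over the list alone (camera adjusted p = 0.92; the list's median was -0.098 and its mean 0.15). In fatty acid synthesis limma called 0 of 24 (0 adjusted over the list alone; camera adjusted p = 0.70), with Mecr at 0.82 (adjusted p = 0.22) and Elovl5 at -0.32 (adjusted p = 0.14). In cholesterol synthesis limma called 0 of 25 (0 adjusted over the list alone; camera adjusted p = 0.71), with Insig1, which restrains sterol synthesis, at 0.81 (limma adjusted p = 0.071, edgeR adjusted p = 0.014) and Sc5d at 0.33. Glycerolipid synthesis had 1 of 35 lower, the phosphatidate phosphatase Lpin1 (61.1 against 96.6 CPM, -0.68, adjusted p = 0.029; 0 and 1 adjusted over the list alone; camera adjusted p = 0.060). Fatty acid oxidation had 0 of 28 (0 adjusted over the list alone; camera adjusted p = 0.92), with Acox3 at 0.70 and Acadvl at -0.51. In oxidative phosphorylation Uqcrh (0.40) rose and Sdhb (-0.41) and Ndufv3 (-0.48) fell among 76 (1 and 2 adjusted over the list alone; camera adjusted p = 0.74; median 0.00064, mean -0.017). Of 7 genes of the mitochondrial genome 0 passed, with 0 adjusted over the list alone (adjusted p = 0.74; mt-Nd2 at 0.15). The calls of Lpin1 (4 of 6 fits without 1 library, adjusted p up to 0.18), Uqcrh (5, 0.18) and Sdhb (5, 0.14) were not kept throughout. Over all genes of this comparison 2225 had an unadjusted p under 0.05, against 708 by chance, and edgeR called 1066.

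Glycolysis genes were lower in Treg where they passed: the glucose transporter Slc2a3 (111 against 246 CPM, -1.14), the lactate transporter Slc16a1 (-0.55), Pfkp (-0.44) and Pkm (-0.39) of 24 fell and 0 rose. The counts were 0 and 4 adjusted over the list alone (camera adjusted p = 6.6e-05, and adjusted p = 0.37 with an estimated correlation). Fits without 1 library lost the calls of Pkm (6 of 6, adjusted p up to 0.23), Slc16a1 (5, 0.16) and Pfkp (4, 0.24). Interferon response genes fell together, 23 of 28 with 0 rising (0 and 27 adjusted over the list alone; median -1.23; camera adjusted p = 2.7e-34, and adjusted p = 0.0012 with an estimated correlation). Among them were Isg15 (12.8 against 126 CPM, -3.24), Ifi44 (14.0 ± 5.82 against 255 ± 23.9, -4.17), Ifi27l2a (285 against 651, -1.19) and Trim30a (167 against 378, -1.18). Of the integrated stress response 8 of 18 fell and 0 rose (0 and 12 adjusted over the list alone; camera adjusted p = 1.7e-10, and adjusted p = 0.016 with an estimated correlation). Those that fell included the transcription factors Ddit3 (25.6 against 106 CPM, -2.00) and Atf4 (-0.66), the amino acid transporter chain Slc3a2 (-0.71) and Mthfd2 (-0.63). Of the immediate early genes Jun (146 against 52.9 CPM, 1.45), Jund (448 against 176, 1.34), Fosb (1.15), Ier2 (0.65) and Junb (0.63) rose and 0 of 16 fell. This made 5 and 2 adjusted over the list alone (camera adjusted p = 0.021, and adjusted p = 0.34 with an estimated correlation). Ier2 lost its call in 4 of 6 fits without 1 library (adjusted p up to 0.20). Trp53inp1 (189 against 109 CPM, 0.79) was the 1 p53 target of 21 to pass. The list gave 2 and 0 adjusted over the list alone (camera adjusted p = 0.81; median -0.13, mean 0.0019). Cell cycle genes had 0 of 35 past the threshold (0 adjusted over the list alone; camera adjusted p = 0.71; Pcna at 0.25). The lectin receptor Klrd1 (14.8 against 1.89 CPM, 2.44) was the 1 of 8 markers of CD8, NK and gamma-delta cells that rose. This made 1 and 0 adjusted over the list alone (camera adjusted p = 0.56). No marker of B cells (0 of 10, camera adjusted p = 0.92), myeloid cells (0 of 9, adjusted p = 0.80) or red cells (0 of 5, adjusted p = 0.79) passed in limma, with 0 in each adjusted over the list alone.

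**Figure D2:**
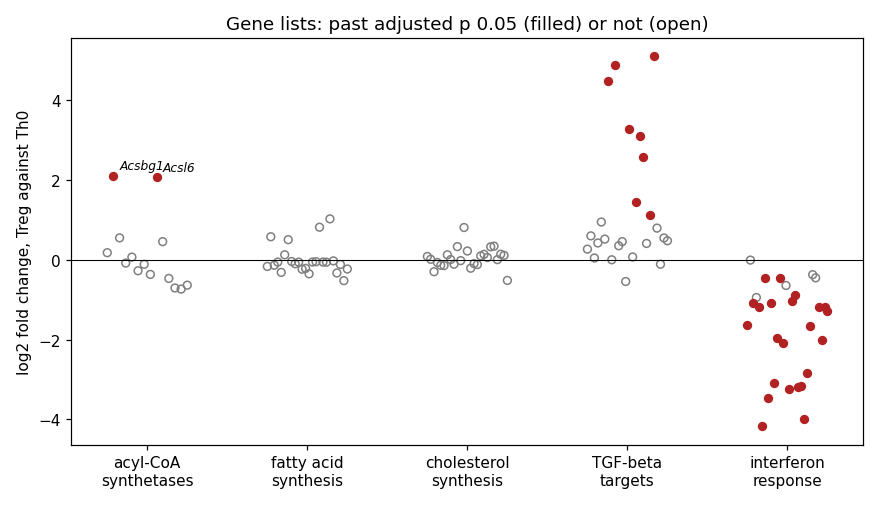
Log2 fold change of Treg against Th0 (axis with values) for the measured members of 5 lists, filled where the limma adjusted p was below 0.05 and open where not, with Acsbg1 and Acsl6 labelled. TGF-beta targets had 8 filled points above 0 and interferon response genes 23 below 0, and fatty acid and cholesterol synthesis had 0.

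Genes higher in Treg than in both Th0 and naive cells were counted because the series asks what is specific to Treg. They included Acsbg1, Acsl6, Foxp3, 6 more of the 27 Treg core genes (Capg, Entpd1, Ikzf4, Itgae, Lrrc32, Nt5e), 5 of 24 TGF-beta targets (Itgae, Ldlrad4, Pmepa1, Skil, Spsb1) and 3 of 17 tissue Treg genes (Bhlhe40, Cxcr6, Itgae). Further members were Uqcrh of oxidative phosphorylation, Runx3 of the effector genes, and Igfbp4 and Treml2 of the naive and quiescence genes. No gene of fatty acid, cholesterol or glycerolipid synthesis, fatty acid oxidation, glycolysis or the cell cycle was among them. The count by limma was 224 (edgeR 319), against 98.7 expected for independent contrasts. Both contrasts used the same 3 Treg libraries, and their changes had a correlation over genes of 0.24, where simulated data without effects gave 0.50 and a highest overlap of 0 in 100 simulations (covariance 0.179 against 0.0853). No gene differed in the simulations, so an overlap of 0 was nearly fixed beforehand. The 98.7 leaves the shared libraries out, so neither number shows how much of the 224 they give. Against naive cells Cxcr6 lost its call in 3 of 6 fits without 1 library (adjusted p up to 0.14). The count was 128 without Treg replicate 2, 143 without Treg replicate 3 and 149 without the trend.

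Both cultures were compared with naive cells, which had not been cultured. The naive libraries held Foxp3 (87.8 CPM) and markers of other blood cells (Hbb-bs 324, Cd74 28.8). A fall therefore cannot tell loss of such cells from change within cells. Lipid synthesis genes rose in both: Scd2, a desaturase of fatty acids, had 1045 CPM in Treg and 1065 in Th0 against 39.6 in naive cells, fatty acid synthase (Fasn) had 406 and 424 against 75.5, and the sterol pathway enzyme Hmgcs1 had 753 and 816 against 79.9. In Treg 13 of 24 fatty acid synthesis genes rose and 0 fell (13 and 0 adjusted over the list alone; camera adjusted p = 5.4e-07, and adjusted p = 0.016 with an estimated correlation). These included Scd2 (4.71), Elovl6 (199 against 6.11 CPM, 4.83), Fasn (2.44) and Acly (1.75). In Th0 15 rose and 0 fell (the same adjusted over the list alone; camera adjusted p = 1.8e-07, and 0.013 with an estimated correlation). Of 25 cholesterol synthesis genes 24 rose in Treg, such as Hmgcs1 (3.23), and 23 in Th0, and 0 fell in either. The counts were the same adjusted over the list alone (camera adjusted p = 6.4e-16 and 1.1e-14). In the acyl-CoA synthetases Acsl6, Acsbg1 (2.53), Aacs (2.30), Acsl4 (177 against 47.4 CPM, 1.88), Acsl3 (88.6 against 25.2, 1.78), Acsf2 (1.75) and Acsl5 (150 against 44.3, 1.74) rose in Treg and Acss1 (-1.52) fell among 14. This made 7 and 1 adjusted over the list alone (camera adjusted p = 0.024, and adjusted p = 0.27 with an estimated correlation). In Th0 Acsl5 (194 CPM, 2.11), Acsl3 (2.05), Acsl4 (1.99), Aacs (2.12) and Acsl6 rose and Acss1 (-1.98) fell. The list gave 5 and 1 adjusted over the list alone (camera adjusted p = 0.030, and adjusted p = 0.24 with an estimated correlation). Glycerolipid synthesis had 10 higher and 5 lower of 35 in Treg, the latter Chka (-2.90), Pisd (-1.25), Lclat1 (-1.08), Chkb (-0.76) and Cdipt (-0.65). The counts were 10 and 5 adjusted over the list alone (camera adjusted p = 0.80). In Th0 12 were higher and 4 lower, Chka (-2.79), Chkb (-0.87), Cdipt (-0.82) and Taz (-0.55). This made 14 and 5 adjusted over the list alone (camera adjusted p = 0.20). Fatty acid oxidation had 9 of 28 higher and 0 lower in Treg, with Acadl at 1.37 (8 and 0 adjusted over the list alone; camera adjusted p = 0.26), where the list's median of 0.18 turned to -0.023 under quantile scaling. In Th0 10 were higher and 1 lower, Hadhb (-0.60). The list gave 10 and 1 adjusted over the list alone (camera adjusted p = 0.34). Calls lost in fits without 1 library were those of Acsf2 (2 of 6, adjusted p up to 0.065), Chkb (2, 0.14), Lclat1 (2, 0.11) and Pisd (without Treg replicate 1, 0.059) in Treg, and of Taz (4, 0.14), Hadhb (3, 0.20) and Chkb (without naive replicate 1, 0.067) in Th0.

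Genes of the cell cycle, oxidative phosphorylation and glycolysis rose in both cultures against naive cells as well. Of 35 cell cycle genes 35 rose in Treg and in Th0 (35 adjusted over the list alone; camera adjusted p = 2.1e-34 and 3.4e-33), with the topoisomerase Top2a at 3445 and 3326 against 78.5 CPM. In oxidative phosphorylation 65 and 66 of 76 rose and 0 fell (66 and 66 adjusted over the list alone; camera adjusted p = 2.7e-17 and 1.0e-16), with Cox5a at 1.81 in Treg. In glycolysis 21 and 22 of 24 rose and 0 fell (22 and 22 adjusted over the list alone; camera adjusted p = 2.0e-14 and 6.1e-16), with Tpi1 at 3.93 in Treg and 4.21 in Th0. The Treg list had adjusted p = 0.064 with an estimated correlation. Of 7 genes of the mitochondrial genome mt-Nd1, mt-Nd2, mt-Nd6 and mt-Co1 rose in both (5 and 4 adjusted over the list alone; camera adjusted p = 0.024 and 0.041). These lists had adjusted p = 0.15 and 0.17 with an estimated correlation. The integrated stress response had 13 of 18 higher in Treg and 2 lower, Ddit3 (-1.99) and Atf4 (-0.42). The counts were 13 and 2 adjusted over the list alone (camera adjusted p = 0.00066, and adjusted p = 0.088 with an estimated correlation). In Th0 16 were higher and 0 lower. This made 17 and 0 adjusted over the list alone (camera adjusted p = 3.4e-08, and adjusted p = 0.013 with an estimated correlation). Interferon response genes had 20 of 28 higher in Th0 and 0 lower (20 and 0 adjusted over the list alone; camera adjusted p = 5.8e-08), such as Ifi27l2a (2.71) and Isg20 (114 against 9.68 CPM). In Treg 8 were higher and 7 lower. The list gave 8 and 7 adjusted over the list alone (camera adjusted p = 0.96; median 0.28, mean -0.038). Among p53 targets 6 of 21 rose and 7 fell in Treg, with Rps27l at 2.57 and Btg2 at -2.22, and 9 rose and 7 fell in Th0. The counts were 7 and 7, 9 and 7 adjusted over the list alone (camera adjusted p = 0.95 and 0.94). Their medians of 0.19 and 0.53 and means of 0.22 and 0.21 were positive where the camera test pointed down.

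Genes of naive and quiescent T cells fell in both cultures against naive cells, 20 of 23 in Treg and 20 in Th0, such as Tcf7 (38.4 against 451 CPM in Treg) and Btg1 (134 against 1333). Those that rose were Treml2 (1.55 in Treg, 0.57 in Th0), Id3 (1.05 and 0.53) and, in Treg, Igfbp4 (0.73). The counts were 3 and 20 in Treg and 2 and 21 in Th0 adjusted over the list alone (camera adjusted p = 2.0e-14 and 6.1e-16). Immediate early genes fell, 12 of 16 in Treg and 13 in Th0, such as Junb (157 against 1809 CPM in Treg). Ier3 (3.16 and 3.27), Hsp90aa1 (0.64 and 0.94) and, in Th0, Atf3 (1.98) rose, and the counts were the same adjusted over the list alone (camera adjusted p = 5.5e-08 and 6.6e-09). Treg core genes had 15 of 27 higher and 6 lower in Treg (15 and 6 adjusted over the list alone; camera adjusted p = 0.0016, and adjusted p = 0.10 with an estimated correlation). Among those higher were the IL-2 receptor chain Il2ra at 1332 against 75.4 CPM and Lrrc32 at 315 against 5.29. In Th0 11 were higher and 9 lower, Foxp3 among the latter at -2.99. This made 11 and 11 adjusted over the list alone (camera adjusted p = 0.22; median -0.0016, mean 0.44). TGF-beta targets fell in Th0, 15 of 24 with Cdkn1a (343 against 21.4 CPM), Pdgfa (1.29) and Id3 rising (3 and 15 adjusted over the list alone; camera adjusted p = 6.4e-06, and adjusted p = 0.013 with an estimated correlation). Pdgfa lost its call in 6 of 6 fits without 1 library (adjusted p up to 0.13). Smad7 (14.5 against 214 CPM) and Skil (-2.17) were among those that fell. In Treg 7 were higher and 7 lower (7 and 7 adjusted over the list alone; camera adjusted p = 0.80; median -0.23, mean 0.15, test pointing down), with Pmepa1 at 2.99 and Smad7 at -1.24. Tissue Treg genes had 7 of 17 higher and 7 lower in Treg and 6 and 7 in Th0. The list gave the same counts adjusted over the list alone (camera adjusted p = 0.96 and 0.86; medians -0.31 and -0.44, means 0.35 and 0.16). Effector genes had 6 of 25 higher and 9 lower in Treg and 9 and 8 in Th0 (7 and 9, 10 and 8 adjusted over the list alone; camera adjusted p = 0.46 and 0.99), with a list median in Th0 that turned to -0.018 under quantile scaling. Gzmb had 499 against 2.91 CPM in Th0, and Eomes 143 against 14.2 in Treg.

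Markers of other blood cells were lower in both cultures than in naive cells. Hemoglobin beta (Hbb-bs) had 324 ± 121 CPM in naive cells, 0.21 in Treg and 0 in all 3 Th0 libraries, and all 5 red cell markers measured (Hba-a1, Hba-a2, Hbb-bt, Hbb-bs, Alas2) fell in both (5 adjusted over the list alone; camera adjusted p = 1.1e-06 and 2.5e-06), with adjusted p = 0.088 and 0.082 with an estimated correlation. B cell markers fell, 8 of 10 in Treg and 10 in Th0 (10 and 10 adjusted over the list alone; camera adjusted p = 3.3e-05 and 4.2e-05, 0.22 and 0.20 with an estimated correlation). So did 7 of 9 myeloid markers in each (7 and 7 adjusted over the list alone, with 1 rising in Treg; camera adjusted p = 0.0024 and 0.0016, 0.18 and 0.16 with an estimated correlation). Of 8 markers of CD8, NK and gamma-delta cells Tcrg-C1 rose in both, and Ncr1, Klrb1c and Trdc fell in both with Cd8b1 in Treg and Klrd1 in Th0 (1 and 4 adjusted over the list alone in each; camera adjusted p = 0.25 and 0.066). Cd8b1 lost its call in Treg without naive replicate 2 (adjusted p = 0.066), and Klrb1c in Th0 in 4 of 6 fits without 1 library (up to 0.096). Among all genes, Ifitm3 (1079 ± 108 against 6.52 CPM) and Prnp (490 against 4.43) were among the largest increases in Treg and Ly6c2 (636 against 6.52) and Bnip3 (291 against 3.25) in Th0, and the nuclear receptor Nr4a1 fell to 8.76 from 265 CPM in Treg. With limma 3305 genes were higher and 2343 lower in Treg than in naive cells, and 3442 and 2493 in Th0. With quantile scaling, which lowered the median change of all genes by 0.126 in Treg and 0.115 in Th0, the counts were 2735 and 2833, and 2872 and 3031.

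In the Smad experiment the targeted genes were read first, and 3' tags do not show whether a guide edited its gene. Smad2 had 37 and 29 CPM in the control libraries, 12 and 24 with sgSmad2, 25 and 30 with sgSmad3, and 13 and 18 with sgSmad2/3. Its change was -0.91 (SE 0.32, limma adjusted p = 1) with sgSmad2 and -1.05 (adjusted p = 0.22; edgeR adjusted p = 0.040 on genes at 1 CPM and 0.16 at 5 CPM) with sgSmad2/3, and adjusted over the 5 genes alone p was 0.040 and 0.0082. Smad3 had 30 and 34 CPM in the control, 44 and 56 with sgSmad2, 26 and 25 with sgSmad3, and 41 and 37 with sgSmad2/3. Its change with sgSmad3 was -0.31 (limma adjusted p = 0.63), and with sgSmad2 0.62 (adjusted p = 1; 0.040 over the 5 genes alone). Foxp3 had 177 and 320 CPM in the control, 214 and 393, 198 and 257, and 189 and 195 with the 3 guides in the order above, and limma called no change (0.28, -0.077 and -0.31).

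Acsl6, the gene the series asks about, had 27 and 27 CPM with sgSmad3 against 75 and 68 in the control, 82 and 78 with sgSmad2, and 31 and 43 with sgSmad2/3. It was 2.59-fold lower with sgSmad3 than in the control (-1.37, SE 0.22, limma adjusted p = 0.027 with the 5 CPM filter; edgeR adjusted p = 1.4e-05 on genes at 1 CPM and 0.032 at 5 CPM; 4.6e-05 over the 5 genes alone) and lower than with sgSmad2 (-1.53, SE 0.22, adjusted p = 0.025). The sgSmad3 call was lost without control replicate 1 (adjusted p = 0.34), control replicate 2 (0.21), sgSmad3 replicate 1 (0.29) or sgSmad3 replicate 2 (0.072), without the trend (0.32), with the compared groups alone (0.52) and without the first control and sgSmad2 libraries (0.60), in a range of 1.4e-05 to 0.60. The call against sgSmad2 was lost in 4 of 4 fits without 1 library (adjusted p 0.071 to 0.28). With sgSmad2/3 the change of Acsl6 was -0.95 (SE 0.22, limma adjusted p = 0.068; edgeR adjusted p = 0.011 and 0.046 in the same order; 0.0015 over the 5 genes alone), and with sgSmad2 0.16 (adjusted p = 1). Between sgSmad2/3 and sgSmad3 it differed by 0.42 (adjusted p = 0.998). Acsbg1 had 35 and 31 CPM with sgSmad2/3 against 69 and 63 in the control (-0.98, SE 0.23, limma adjusted p = 0.079; edgeR adjusted p = 0.0073 and 0.067; 0.0015 over the 5 genes alone), 46 and 46 with sgSmad3 (-0.51, adjusted p = 0.43), and 54 and 86 with sgSmad2 (0.048, adjusted p = 1).

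With sgSmad2, 1 gene changed: Myo6, an actin motor, had 159 and 183 CPM against 69 and 70 in the control (1.28, SE 0.18, limma adjusted p = 0.027 with the 5 CPM filter). That call was lost in all 4 fits that left out a library, without control replicate 1 (adjusted p = 0.76), control replicate 2 (0.62), sgSmad2 replicate 1 (0.15) and sgSmad2 replicate 2 (0.64), as well as without the trend (0.87) and without the first control and sgSmad2 libraries (0.91). No list had a member past the threshold. Cholesterol synthesis genes had a median of -0.20 with Hmgcs1 at -0.48 (camera adjusted p = 0.00016 for the list, and adjusted p = 0.73 with an estimated correlation; 0 of 25 adjusted over the list alone), and the mitochondrial genome a median of -0.22 (camera adjusted p = 0.033, and adjusted p = 0.73 with an estimated correlation; 0 of 7 adjusted over the list alone). The other 19 lists tested had camera adjusted p of 0.11 to 0.94, with 1 member each of the tissue Treg, CD8 and NK, and red cell lists past the threshold adjusted over the list alone. The test pointed down for acyl-CoA synthetases (median 0.027, mean -0.0058) and fatty acid synthesis (0.040 and 0.020), and up for CD8 and NK markers (-0.16 and -0.14). The fit as planned called 0 genes in limma (1006 with an unadjusted p under 0.05, 917 by chance), which on these rounded values is no evidence of no change, and edgeR called 24 on genes at 1 CPM and 1 at 5 CPM.

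With sgSmad3, Acsl6, the translation factor Eif4a2 (21 and 27 against 58 and 59 CPM, -1.26), Fchsd2 (64 and 59 against 123 and 141, -1.09) and Diaph2 (-0.95) fell. Integrin beta 3 (Itgb3, 44 and 42 against 14 and 15 CPM, 1.51), Myo6 (180 and 171 against 69 and 70, 1.32), Ms4a6b (1.23), Nup93 (1.09), Farsa (1.03) and the predicted gene Gm23639 (1.27), chosen after its values were seen, rose. Acsl6 was the 1 of 12 acyl-CoA synthetases to fall. The counts were 0 and 1 adjusted over the list alone (camera adjusted p = 0.12). No member of the Treg core (camera adjusted p = 0.080), TGF-beta target (0.052), fatty acid synthesis (0.75), cholesterol synthesis (0.88; median -0.022, mean 0.021), glycerolipid synthesis (0.73) or fatty acid oxidation (0.73) lists passed, and 0 did adjusted over the list alone. Cell cycle genes had 0 of 35 past the threshold (5 higher and 0 lower adjusted over the list alone) and a median of 0.28 (camera adjusted p = 4.6e-07, and adjusted p = 0.19 with an estimated correlation), with Plk1 at 0.75 and Mcm2 at 0.65. Red cell markers had 0 of 4 past the threshold (2 and 0 adjusted over the list alone; camera adjusted p = 0.0069, and adjusted p = 0.73 with an estimated correlation). The other 12 lists tested had 0 members past the threshold and camera adjusted p of 0.15 to 0.83. Adjusted over the list alone these gave 1 and 0 for tissue Treg genes, 0 and 1 each for glycolysis and effector genes, 2 and 1 for naive and quiescence genes, 2 and 0 each for the integrated stress response and myeloid markers, 1 and 0 for CD8 and NK markers, and 0 for the others. Oxidative phosphorylation had a median of 0.014 and a mean of -0.00027. These sgSmad3 libraries held transcripts of small intestine at 349 and 31 CPM, against 10 and 14 in the control. The 10 genes called with the 5 CPM filter became 0 without control replicate 1, control replicate 2 or sgSmad3 replicate 1, 6 without sgSmad3 replicate 2, of which Ms4a6b was the 1 gene named here (adjusted p = 0.023), 2 without the trend, and 0 with the compared groups alone or without the first control and sgSmad2 libraries. The fit as planned called 0 in limma (1842 with an unadjusted p under 0.05) and edgeR 185 on genes at 1 CPM and 15 at 5 CPM.

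With sgSmad2/3, Gzmb, Itgb3, Id2 and Ccr2 rose, and Nt5e, Cd40, Nlrp6 and Pmepa1, which were higher in Treg than in Th0, fell. Gzmb had 95 and 76 CPM against 14 and 10 in the control (2.74, SE 0.30, limma adjusted p = 0.00021), Itgb3 88 and 106 against 14 and 15 (2.66, SE 0.25, adjusted p = 9.3e-05), Id2, an inhibitor of basic helix-loop-helix factors, 619 and 548 against 185 and 204 (1.58, SE 0.16, adjusted p = 0.00010). Its relative Id1 had 32 and 37 against 3 and 7, Myo6 204 and 283 against 69 and 70 (1.78, SE 0.18), and the chemokine receptor Ccr2 30 and 26 against 1 and 2. The adenosine-producing enzyme Nt5e fell to 21 and 32 from 66 and 68 CPM (-1.34, SE 0.23, limma adjusted p = 0.010), Cd40 to 11 and 17 from 42 and 43 (-1.57, adjusted p = 0.0094), Nlrp6 to 16 and 24 from 64 and 49 (-1.47), Pmepa1 to 343 and 381 from 647 and 662 (-0.85, SE 0.15, adjusted p = 0.013), Skil to 201 and 192 from 320 and 391 (-0.85), the NAD-consuming enzyme Cd38 to 5 and 4 from 19 and 19 (-1.87) and Tnfsf11, the cytokine RANKL (-2.20). In all 25 genes rose and 31 fell with the 5 CPM filter. The total of 56 was 13 and 10 without control replicate 1 and 2, 4 and 4 without sgSmad2/3 replicate 1 and 2, and 0 without the trend, with the compared groups alone or without the first control and sgSmad2 libraries. Itgb3, Id2 and Myo6 kept their call in every fit that left out 1 library, but not in those 3 (adjusted p = 0.054, 0.063 and 0.063 without the trend). Gzmb lost it without sgSmad2/3 replicate 1, Ccr2 and Id1 without either sgSmad2/3 library, and Nt5e, Cd40, Nlrp6, Pmepa1, Skil, Cd38 and Tnfsf11 without any 1 of the 2 control or 2 sgSmad2/3 libraries. The fit as planned called 0 in limma (1795 with an unadjusted p under 0.05) and edgeR 201 on genes at 1 CPM and 71 at 5 CPM.

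By list, sgSmad2/3 had Id2, Ccr2 and Gzmb higher and Maf (-1.17) lower among 15 tissue Treg genes. The list gave 5 and 3 adjusted over the list alone (camera adjusted p = 0.28; median -0.055, mean 0.40). TGF-beta targets had Pmepa1 and Skil lower and Id1 higher among 21 (2 and 5 adjusted over the list alone; camera adjusted p = 0.024 downward, and adjusted p = 0.48 with an estimated correlation). Nt5e was the 1 of 23 Treg core genes to fall. The counts were 2 and 3 adjusted over the list alone (camera adjusted p = 0.28). Gzmb of 14 effector genes (1 and 1 adjusted over the list alone; camera adjusted p = 0.86) rose, and so did Dapl1 (1.51) of 23 naive and quiescence genes (3 and 1 adjusted over the list alone; camera adjusted p = 0.41). The calls of Pmepa1, Skil, Nt5e and Maf (0.12 to 0.71) were lost in 4 of 4 fits without 1 library, that of Dapl1 in 3 (up to 0.17), those of Id1 and Ccr2 in 2 and that of Gzmb in 1. The lipid lists had no member past the threshold: acyl-CoA synthetases (0 of 12, 1 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.23), fatty acid synthesis (0 of 22, adjusted p = 0.28), cholesterol synthesis (0 of 25, adjusted p = 0.36), glycerolipid synthesis (0 of 31, adjusted p = 0.63) and fatty acid oxidation (0 of 26, adjusted p = 0.42), the last 4 with 0 adjusted over the list alone. Cell cycle genes had 0 of 35 past the threshold (4 and 0 adjusted over the list alone) with a median of 0.28 (camera adjusted p = 3.7e-08, and adjusted p = 0.14 with an estimated correlation). Immediate early genes had 0 of 13 (5 lower adjusted over the list alone; camera adjusted p = 0.00051 downward, and adjusted p = 0.48 with an estimated correlation), with Egr1 at -1.50 (adjusted p = 0.074), and glycolysis 0 of 23 (0 adjusted over the list alone; camera adjusted p = 0.018, and adjusted p = 0.48 with an estimated correlation). Red cell markers had 1 of 4 higher, Hba-a1 (50 and 70 against 12 and 12 CPM; 3 adjusted over the list alone; camera adjusted p = 4.2e-06, and adjusted p = 0.30 with an estimated correlation), a call lost without sgSmad2/3 replicate 2 (adjusted p = 0.073). Myeloid markers had 0 of 3 (3 adjusted over the list alone; camera adjusted p = 0.0018, and adjusted p = 0.28 with an estimated correlation), with S100a9 at 3.63 (adjusted p = 0.075). No member of oxidative phosphorylation (camera adjusted p = 0.36), the mitochondrial genome (0.11), interferon response (0.33), p53 targets (0.28), integrated stress response (0.081) or CD8 and NK markers (0.77; median 0.14, mean -0.099) passed. Adjusted over the list alone, p53 targets gave 1 and 0, CD8 and NK markers 1 and 1, and the other 4 lists 0. A single B cell marker was measured, too few for a test. The sgSmad2/3 libraries held small intestine transcripts at 86 and 26 CPM.

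Differences between the guides were tested directly. Id2 and Gzmb were the 2 genes that differed between sgSmad2/3 and sgSmad3 with the 5 CPM filter, both higher with sgSmad2/3 (1.42, limma adjusted p = 0.00094, and 2.47, adjusted p = 0.0017; edgeR called 40 on genes at 1 CPM). Against sgSmad2, Gzmb (1.88), Id2 (1.49) and Hba-a1 (1.42) were higher and Cd40 (-1.90), Ncmap (-1.56), Ubash3b (-1.31), Nt5e (-1.29), Endod1 (-1.20), Fchsd2 (-1.19), Diaph2 (-1.06) and Pmepa1 (-0.90) lower with sgSmad2/3. Between the single guides, Cd40 (-1.66), Acsl6 (-1.53), Ncmap (-1.50), Endod1 (-1.26) and Fchsd2 (-1.10) were lower with sgSmad3. None of these calls was kept in all 4 fits without 1 library of the groups compared, each of which left 1 library in a group. No gene departed from the sum of the single guides in limma, as planned (1051 with an unadjusted p under 0.05) or with the 5 CPM filter (312, smallest adjusted p = 0.19), and edgeR called 10 on genes at 1 CPM and 0 at 5 CPM. Id2 departed by 1.32 (SE 0.22, limma adjusted p = 0.19; edgeR adjusted p = 0.0014 on genes at 1 CPM), and Acsl6 by 0.26 (adjusted p = 1). In that contrast cholesterol synthesis had a median of 0.25 and glycolysis of 0.14 (camera adjusted p = 0.00035 and 0.032, and adjusted p = 0.64 with an estimated correlation for both; 0 adjusted over the list alone). The guides shared 2 control libraries, too few to give 2 to each comparison, so part of the likeness may come from them. The changes of sgSmad3 and sgSmad2/3 had a correlation over genes of 0.66 (simulated without effects 0.50) and a covariance of 0.131 (simulated 0.0688), with 4 shared higher and 2 shared lower genes against 0.014 and 0.012 expected for independent contrasts and at most 0 in 100 simulations. Those of sgSmad2 had correlations of 0.46 with sgSmad3 and 0.50 with sgSmad2/3 and covariances of 0.0739 and 0.0821, with 1 shared higher gene each. No gene differed in the simulations, so their 0 shared genes were nearly fixed beforehand. The counts expected for independent contrasts leave the shared controls out. Neither shows how many shared genes the 2 control libraries give.

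The genes that differed between Treg and Th0, cultures with and without TGF-beta, moved the opposite way with the guides. All 3 comparisons subtract the same 2 controls, which had no guide, so a shift in these would move all 3 alike. Comparisons between guides, given below, do not. In the fit as planned, genes 2-fold or more higher in Treg (233, of which 231 were measured) had median changes of -0.18 with sgSmad2, -0.34 with sgSmad3 and -0.68 with sgSmad2/3, and 68.0%, 73.2% and 93.5% of them were lower than in the control (camera p adjusted over the 6 tests 2.7e-07, 1.6e-11 and 2.2e-37; adjusted p = 0.047, 0.024 and 0.0043 with an estimated correlation). Genes lower in Treg (177, of which 172 were measured) had median changes of 0.25, 0.21 and 0.50 (camera adjusted p = 1.4e-05, 0.010 and 1.4e-13; adjusted p = 0.0043, 0.020 and 0.0015 with an estimated correlation). The medians with the 5 CPM filter (212 and 127 measured) were -0.19, -0.35 and -0.70 for the higher set (camera adjusted p = 0.028, 0.015 and 0.0025 with an estimated correlation) and 0.28, 0.23 and 0.55 for the lower (adjusted p = 0.0022, 0.015 and 0.0011). Of the 31 genes called lower with sgSmad2/3 under that filter 26 were in the higher set, and of the 25 called higher 14 were in the lower set. In the fit as planned, the higher set was lower with sgSmad2/3 than with sgSmad2 (median -0.47) and sgSmad3 (-0.33). The camera p, adjusted over the 8 tests between guides, were 7.9e-23 and 3.3e-15 (0.014 and 0.024 with an estimated correlation). The lower set was higher (0.27 and 0.32, camera adjusted p = 2.3e-07 and 6.0e-11). Between the single guides the higher set was lower with sgSmad3 (-0.11, camera adjusted p = 0.0096, and adjusted p = 0.24 with an estimated correlation) and the lower set differed by -0.032 (adjusted p = 0.24). From the sum of the single guides the higher set departed by -0.16 (camera adjusted p = 0.021, and adjusted p = 0.26 with an estimated correlation) and the lower set by 0.16 (camera adjusted p = 0.047). These 8 values were, in the same order with the 5 CPM filter, -0.48, -0.33, 0.26, 0.31, -0.11, -0.050, -0.16 and 0.076 (camera adjusted p = 0.0077, 0.016, 0.0041, 0.0019, 0.14, 0.065, 0.22 and 0.050 with an estimated correlation). In fits as planned without 1 library the higher set had medians of -0.24 to -0.073 with sgSmad2. The lower set with sgSmad3 lost its call without sgSmad3 replicate 2 (median 0.20) or the first control and sgSmad2 libraries (0.17).

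**Figure D3:**
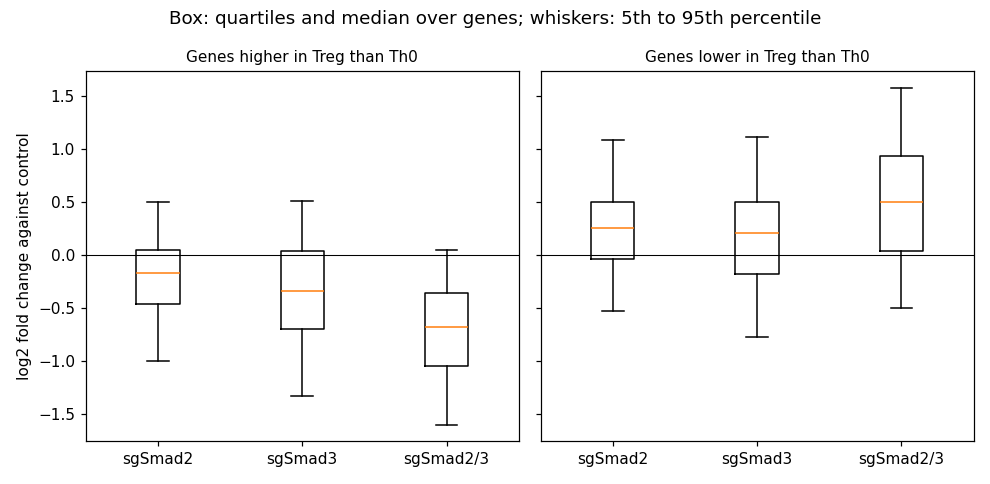
Log2 change against the control (vertical axis) with sgSmad2, sgSmad3 and sgSmad2/3 for genes higher in Treg than in Th0 (left) and lower (right), as boxes of quartiles and median over genes with whiskers from the 5th to the 95th percentile. The medians in the fit as planned were -0.18, -0.34 and -0.68 on the left and 0.25, 0.21 and 0.50 on the right.

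Transcripts of other tissues were present in single Smad libraries, and those of small intestine and skeletal muscle were highest in the first sgSmad3 library. The summed level of 4 lists was higher in all 4 libraries with the sgSmad3 guide than in all 4 without it. Small intestine transcripts were at 349 and 31 CPM with sgSmad3 and 86 and 26 with sgSmad2/3, against 10 and 14 in the control and 5 and 11 with sgSmad2. In the first sgSmad3 library the defensin Defa24 had 74 CPM, the antimicrobial lectin Reg3b 49, the mucin Muc2 42 and the fatty acid binding protein Fabp2 39. Liver transcripts were at 37 and 9 with sgSmad3 and 56 and 12 with sgSmad2/3, against 1 to 3 in the others. Red cell transcripts were at 87, 33, 70 and 144 CPM in these 4 libraries against 13 to 26, and granulocyte transcripts at 63, 11, 17 and 67 against 0 to 6. The other 7 lists did not follow the guide: skeletal muscle transcripts were at 226 CPM in the second sgSmad2 library, and salivary gland transcripts at 43 and 89 in the control libraries. In cell-type cultures intestine transcripts reached 7.8 CPM and liver transcripts 1.9. Of the called genes, 0 of 10 with sgSmad3 and 1 of 56 with sgSmad2/3 (Hba-a1) were on these lists. The lists were written after the Smad table had been seen and lack the called collagen gene Col1a1, so they may miss such calls.

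**Figure D4:**
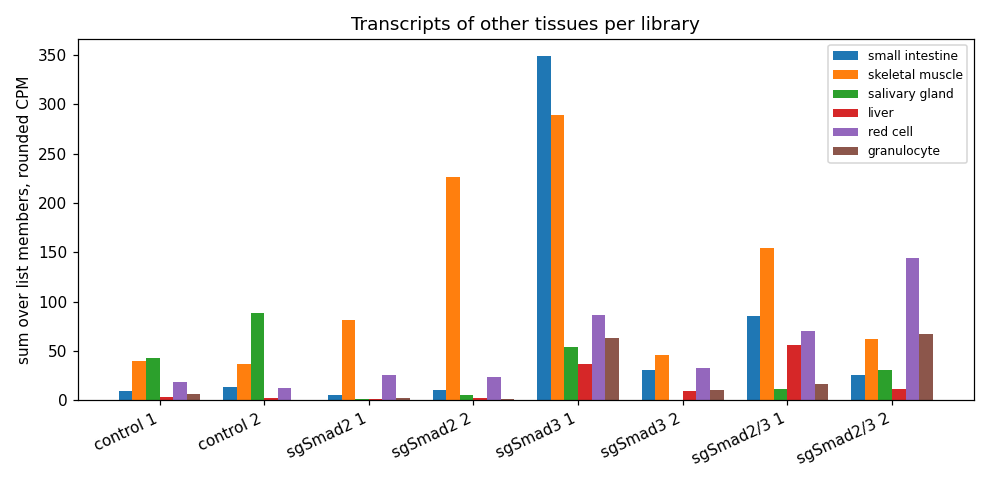
Summed level of transcripts of other tissues and blood cells in rounded CPM (bars from 0) in each of the 8 Smad libraries, by list. Intestine transcripts reached 349 CPM in the first sgSmad3 library and at most 14 in the control and sgSmad2 libraries.

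Each guide was also compared over both backgrounds (4 libraries with it against 4 without), a contrast added after the single ones gave no gene in the fit as planned. With the sgSmad3 guide Acsl6 had 32.0 ± 7.57 CPM against 75.8 ± 5.91 (-1.24, SE 0.15, limma adjusted p = 0.00099 with the 5 CPM filter), and it was past the threshold in all 8 fits that left out 1 library, but not without the trend (adjusted p = 0.090) or without the first control and sgSmad2 libraries (0.53). Acsbg1 had 39.5 ± 7.68 CPM against 68.0 ± 13.5 (-0.77, SE 0.16, limma adjusted p = 0.033), a call lost without control replicate 1 (adjusted p = 0.17), control replicate 2 (0.082), sgSmad2 replicate 2 (0.060), sgSmad3 replicate 1 (0.12), sgSmad3 replicate 2 (0.082), sgSmad2/3 replicate 1 (0.24) or sgSmad2/3 replicate 2 (0.25). These were the 2 of 12 acyl-CoA synthetases to fall. The list gave 1 and 2 adjusted over the list alone (camera adjusted p = 0.066). Cd40 (15.3 against 48.3 CPM, -1.61, SE 0.19, limma adjusted p = 0.00061), Cd38 (4.25 against 17.0, -1.77; adjusted p = 0.055 without sgSmad2/3 replicate 2), Nt5e (33.3 against 66.0, -1.01), Itgae (19.0 against 42.5, -1.12) and Pmepa1 (439 against 665.5, -0.62) fell, and Id2 (400.5 against 201 CPM, 0.82) and Ly6e (483 against 253, 0.97) rose. Plk1 (0.56) and Mcm2 (0.56) were the 2 of 35 cell cycle genes to rise. The counts were 10 and 0 adjusted over the list alone (camera adjusted p = 6.6e-09, and adjusted p = 0.12 with an estimated correlation). Cd40 kept its call in all 8 fits without 1 library, but not without the trend (adjusted p = 0.080) or without the first control and sgSmad2 libraries (0.53). Calls were lost for Id2 (without sgSmad2/3 replicate 1, adjusted p = 0.080), Nt5e (2 fits, up to 0.15), Pmepa1 (3, 0.20), Itgae (4, 0.15), Ly6e (5, 0.27), Plk1 (6, 0.29) and Mcm2 (7, 0.31). With the sgSmad2 guide Gzmb (54.0 against 13.5 CPM, 1.67, limma adjusted p = 0.0049), Ccr2 (1.90), Itgb3 (1.34), Dapl1 (0.94), Myo6 (0.87) and Id2 (0.75) rose and Tjp1 (-1.17) fell. All of these lost their call in some fits: Gzmb and Itgb3 in 3 of 8 (adjusted p up to 0.19 for both), Ccr2 (up to 0.53) and Id2 (0.29) in 7, and Dapl1 (0.52), Myo6 (0.38) and Tjp1 (0.52) in 8. With the 5 CPM filter 33 genes rose and 67 fell with sgSmad3, and 10 rose and 1 fell with sgSmad2, of which 3 and 1 were on the lists of other tissues (Hba-a1 in both, Hbb-bs and S100a9 with sgSmad3; with sgSmad3 these lost their call in 1, 6 and 6 fits without 1 library, and Hba-a1 with sgSmad2 in 8). The sgSmad3 total of 100 was 32 and 47 without control replicate 1 and 2, 30 and 260 without sgSmad2 replicate 1 and 2, 23 without sgSmad3 replicate 1, 11 and 9 without sgSmad2/3 replicate 1 and 2, 2 without the trend, and 0 without the first control and sgSmad2 libraries. The sgSmad2 total of 11 lay between 0 and 8 in the fits without 1 library: 2 and 2 (controls 1 and 2), 1 and 4 (sgSmad2), 1 and 8 (sgSmad3), 0 and 0 (sgSmad2/3), and was 0 without the trend and without the first control and sgSmad2 libraries. The fit as planned called 0 in limma for both guides (2355 and 1268 with an unadjusted p under 0.05), and edgeR called 434 and 55 on genes at 1 CPM and 121 and 11 at 5 CPM.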

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

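The 5 CPM filter was planned, and its use chosen after its counts and those of edgeR had been seen. The fits without the first control and first sgSmad2 libraries and without ribosomal RNA genes were added after the data had been seen. The fit as planned on the rounded Smad table failed on simulated data, so its counts of 0 say nothing about change. Of the results compared with their alternatives, 252 list results (guides in the fit as planned) kept direction and side of the threshold, 36 were weaker, 10 stronger and 10 reversed. Guide lists with the 5 CPM filter gave 137, 22, 1 and 8. Named genes of all fits gave 2435, 378, 12 and 25. The gene sets gave 106 and 2 weaker. Of the counts 164 lay within 1.5 times and 31 moved, and with the 5 CPM filter 57 and 54. With 2 libraries per guide a fit without 1 library assumes that the lone sample varies like the other groups. The contrasts between guides were refitted without single libraries for their called genes alone. Rounding to whole CPM limits the Smad table below about 5 CPM. Except where fewer libraries were fitted, the cause was not tested.

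Treg against Th0 gave 453 genes without the trend and 503 to 642 in leave-one-out fits, and Treg-specific genes 149 and 128 to 241. The replicate block gave 759 genes for Treg against Th0, 5630 for Treg against naive, 5897 for Th0 against naive and 217 Treg-specific, and 0 in all guide contrasts as planned. With the 5 CPM filter the block gave 2 for sgSmad2, 27 for sgSmad3, 110 for sgSmad2/3, and 247 and 18 for the pooled sgSmad3 and sgSmad2 guides. Replicate numbers did not pair cell-type libraries.

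For sgSmad2, sgSmad3 and sgSmad2/3 the counts of the fit as planned (0) became 185, 178 and 178 with a pseudocount of 0.1 CPM, 175, 158 and 164 without the trend, 3, 65 and 116 with robust moderation, 1, 10 and 56 with the 5 CPM filter, 24, 185 and 201 with edgeR, and 444, 519 and 508 with the compared groups alone. The departure from additivity became 1 (robust) and 10 (edgeR), the pooled sgSmad3 guide 239, 100 and 434 and the pooled sgSmad2 guide 20, 11 and 55 (robust, 5 CPM filter, edgeR). Leave-one-out fits gave 0 in each.

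With the 5 CPM filter, sgSmad2 gave 2 genes with median-ratio or quantile scaling or robust moderation, 1 with edgeR on the same genes and 0 without the trend, without the first control and sgSmad2 libraries or with the compared groups alone. sgSmad3 gave 2 without the trend, 16 without ribosomal RNA genes, 15 with edgeR and 0 in the last 2. sgSmad2/3 gave 71 with edgeR and 0 in those 3. The departure from additivity gave 0 with edgeR. The pooled sgSmad3 guide gave 2 without the trend, 0 without the 2 libraries and 121 with edgeR, and the pooled sgSmad2 guide 0, 0 and 11. The larger edgeR counts above come from genes at 1 CPM, so they differ from these fits in filter and method. Leave-one-out ranges were 0 to 0 (sgSmad2), 0 to 6 (sgSmad3), 4 to 13 (sgSmad2/3), 0 to 0 (additivity), 9 to 260 (pooled sgSmad3) and 0 to 8 (pooled sgSmad2). In the fit as planned, genes lower in Treg had a median of 0.17 in sgSmad3 without the 2 libraries, and 0.17 to 0.21 in leave-one-out fits.

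Values that changed sign were these. The departure from additivity of Smad2 became -0.54 without the 2 libraries and -0.37 to 0.58 in leave-one-out fits, and that of Smad3 0.0059 without mitochondrial and ribosomal protein genes, 0.015 without ribosomal RNA genes and -0.20 to 0.14 in leave-one-out fits. Leave-one-out fits also turned Acsbg1 with sgSmad2 (-0.28 to 0.38), Foxp3 with sgSmad2 (-0.15 to 0.72), sgSmad3 (-0.50 to 0.35), sgSmad2/3 (-0.73 to 0.12) and the pooled sgSmad2 guide (-0.19 to 0.24), and Smad2 with the pooled sgSmad3 guide (-0.43 to 0.039) and in Th0 against naive (-0.20 to 0.081). Under fry the direction differed for 5 lists of the cell-type experiment, with medians of 0 (B cell markers, Treg against Th0), -0.23 (TGF-beta targets, Treg against naive), 0.19 and 0.53 (p53 targets, Treg and Th0 against naive), -0.44 (tissue Treg genes, Th0 against naive). It differed for 5 guide lists in the fit as planned, with medians in that fit of 0.051 (fatty acid synthesis, sgSmad2), -0.022 (cholesterol synthesis, sgSmad3), -0.037 (acyl-CoA synthetases, sgSmad2/3), and -0.017 and -0.099 (oxidative phosphorylation and mitochondrial genome, additivity). It differed for 8 of the planned contrasts' lists with the 5 CPM filter, with medians of 0.027, -0.030 and -0.16 (acyl-CoA synthetases, p53 targets, CD8 and NK markers, sgSmad2), -0.022, 0.014 and -0.13 (cholesterol synthesis, oxidative phosphorylation, p53 targets, sgSmad3), and -0.018 and 0.016 (oxidative phosphorylation and integrated stress response, additivity), and for 5 in other contrasts, 0.021 and -0.047 (oxidative phosphorylation and interferon response, sgSmad2/3 against sgSmad2), 0.065 (TGF-beta targets, sgSmad2/3 against sgSmad3), -0.013 (fatty acid synthesis, sgSmad3 against sgSmad2) and 0.0029 (oxidative phosphorylation, pooled sgSmad3).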

Other observations

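Of the tests below, the splits of the Treg-specific count and of both pooled guides and the thinning to 1 number of reads were chosen before their results were seen. The bound that decided on depth and the other tests of splits and explanations were chosen after. Gene calls come from the planned contrasts and 5 CPM filter.

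The genes named here are outside the fixed lists and were chosen after their values were seen. The costimulatory receptor Cd28 (1.26) and the annexin Anxa2 (0.97) were higher with sgSmad2/3 than in the control (limma, 5 CPM filter), and the collagen gene Col1a1 had 37 and 17 CPM against 3 and 6. Fits without 1 library of either group lost the calls of Anxa2 (adjusted p 0.083 to 0.41), Prnp (0.065 to 0.29), Sgk1 (0.12 to 0.55) and Tjp1 (0.092 to 0.44) in all 4, and that of Cd28 in 3 (up to 0.30). Col1a1 lost its call without control replicate 1 (adjusted p = 0.23), control replicate 2 (0.065), sgSmad2/3 replicate 1 (0.64) and sgSmad2/3 replicate 2 (0.13). The prion protein gene Prnp (-0.94), the kinase Sgk1 (-1.14) and the junction protein Tjp1 (-1.68) were lower. With the pooled sgSmad3 guide, red cell markers had 2 of 4 higher, Hba-a1 (1.21; call lost in 1 of 8 fits without 1 library, adjusted p = 0.098) and Hbb-bs (2.54; lost in 6, up to 0.31) (4 adjusted over the list alone; camera adjusted p = 1.1e-05, and adjusted p = 0.33 with an estimated correlation). With the pooled sgSmad2 guide the 7 genes of the mitochondrial genome had a median of -0.25, and 0 passed (0 adjusted over the list alone; camera adjusted p = 0.00043, and adjusted p = 0.50 with an estimated correlation).

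Splits of the libraries were counted for each comparison of groups of 3 or more. With 3 against 3 libraries there are 10 splits, too few for a share under 0.05: fitted on 6 libraries, the real splits gave 960, 5605 and 5680 genes for Treg against Th0, Treg against naive and Th0 against naive, each the 1 split with as many, and the highest other split gave 0. For the Treg-specific count of 224, 4 of 100 drawn splits gave as many, and the highest other split gave 1838. A share this near 0.05 from a draw of splits does not exclude chance. The draws also moved the naive libraries, so a drawn split can hold real differences between naive and cultured cells. The share and the 1838 genes therefore decide neither for nor against chance in the Treg count. Fitted as 2 groups with the 5 CPM filter, the sgSmad3 guide pooled over backgrounds gave 133 genes in the real split, against 4 in the highest other. Of 35 splits 1 gave as many, the smallest share possible. Most other splits part the 2 libraries of a guide, which adds any guide effect to the spread. The labels do not say whether these libraries are independent, so chance is not excluded. For the sgSmad2 guide the real split gave 0, 35 of 35 splits gave as many, and the highest other gave 133, which is the sgSmad3 split.

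Genes higher in Treg than in Th0 were lower with sgSmad2/3 (median -0.68 in the fit as planned, -0.70 with the 5 CPM filter). The first control library, which shares deviations with the first sgSmad2 library, is argued against as the source, since the median without the 2 libraries was -0.73. Dilution by transcripts of other tissues is also argued against, since it would lower genes of the T cell receptor complex and its signalling as far, and 16 of them outside the set had a median of 0.23 (quartiles 0.10 and 0.32, 5 CPM filter). A smaller share of converted cells, the rest being like Th0, may account for it: a mixture of 50.8% Th0-like cells predicts -0.93 for Foxp3, where -0.31 (SE 0.27, 5 CPM filter) was seen, 2.32 SE away, but 0.68 SE away without control replicate 1 and 3.61 without control replicate 2, so it stays open. Loss of Smad signalling, the design's biological explanation, stays open and untested. So does carrying a guide RNA, which the control lacked.

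Transcripts of intestine, liver, red cells and granulocytes were present in libraries with the sgSmad3 guide. RNA of other tissues in those libraries is a candidate explanation: 13 intestine genes were above 3 reads in the first sgSmad3 library and at most 9 in any other, with Defa24 at 74 and Reg3b at 49 CPM. The guide itself cannot be told apart from the handling of the libraries, which the labels do not give: 4 of 11 lists were higher in all 4 libraries with the guide than in all 4 without it.

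More genes were above 0 in the first control (16547) and first sgSmad2 (16641) libraries than in the other 6 (14298 to 15499). Depth is argued against as the whole source. The first sgSmad3 library had more reads (1602297) and 15499 genes, and thinning all libraries to 1 number of reads left the gap of 1048 genes at 1053, and at 1041 to 1092 over 20 draws. That gap missed the bound set before, the range of 1060 among the other 6, but that range holds differences other than depth. No biological explanation was tested, since the 2 libraries belong to different groups and share a replicate number.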
